A study of Mus musculus with 2 samples.

How the data were processed

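Sinoatrial node cells marked by an Hcn4-driven nuclear reporter were sorted from neonatal mouse hearts at postnatal day 1 to 3. Per the labels' protocols, chromatin was crosslinked with 2 mM disuccinimidyl glutarate for 30 min and 1% formaldehyde for 10 min. It was sheared to 100 to 400 bp and precipitated with 5 µg of a monoclonal antibody to ISL1. Shearing sets how finely a binding site is resolved. The protein-to-protein crosslinker also captures factors bound through partners, so a peak need not be a direct contact with DNA. The series had 1 ISL1 library and 1 input library. The input library was not analysed here, and no value was computed from its signal. Whether the input shaped the deposited peak list is not known.

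Bowtie and HOMER are named, with the mouse build mm9, per the submitters' processing notes; versions are not given in the sources used here. Per the file headers, the peaks were annotated with HOMER's annotation program on mm9, from a peak table whose name refers to the input. The peak caller's settings, any duplicate filter and the way the input was used are not given in the sources used here. The peaks come from 1 library and not from pooled replicates. The deposited peak score is a number per peak made by the authors, and it was used only to describe, rank and filter peaks within the list. The deposited focus ratio is a fraction between 0.381 and 0.95 with a median of 0.739. The distance to the nearest TSS and the annotation of each peak (promoter, exon, intron, UTR, intergenic) are the authors' own, per the file headers. Promoter annotation, exon numbers and coordinates are given as deposited. A peak is listed under the gene with the nearest TSS, which need not be the gene that contains it or the gene it acts on.

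The number of whole score steps was found by searching for the step whose multiples, rounded to 3 digits, match the scores; 0 of 1483 were off. Intervals at the 95% level are exact: Clopper-Pearson for shares of peaks, Poisson for counts and conditional for odds ratios. They cover counting error only. Total reads were not analysed here, so the depth follows from the score steps alone and under the assumption named with it.

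Genes were matched to a RefSeq gene table of assembly GRCm38.p6 by Entrez identifier; 1002 of 1003 nearest genes matched. As that build differs from mm9, it served only for names, for the background and for the order of neighbouring genes. The background was the 26220 genes with a curated transcript, of which 21031 are protein-coding and 674 were nearest to a peak within 100 kb. No genome sequence was used. For that reason the planned search for binding motifs was not run, nor was a comparison of annotation shares with the genome, nor draws weighted by the genome length around each gene or matched on gene length. Long genes and genes in wide intergenic space collect more peaks by distance alone, and the list tests do not correct for it.

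The tests of the gene lists, of promoter scores, of the upstream and downstream split of all peaks, of grouping and of genes with several peaks were fixed before the data were examined. The split of intergenic peaks alone was not among them. The tests of chromosome X, of exonic peaks and of gene families were chosen after. Each of 16 gene lists was tested by Fisher's exact test, two-sided, for genes nearest to a peak within 100 kb, with Benjamini-Hochberg adjustment over the 16 lists and a threshold of 0.05. All list members were found in the background. Camk2d, Meis2, Nebl and Wnt11 are among the genes that 2 lists share. The difference in median score between promoter and distal peaks was tested by permutation with 100000 resamples. Grouping of peaks was tested with 10000 draws of uniform positions between the first and last peak of each chromosome, and genes with several peaks with 10000 draws over the background; alternatives used 1000 draws. Neither kind of draw models mappability or open chromatin.

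Genes were named by a rule with 5 parts. The rule took the nearest genes of the 10 highest peaks within 100 kb, the 10 genes with the most such peaks, and up to 8 members with a peak from each of the first 3 lists. It also took up to 3 from each other list, and Isl1, Hcn4, Tbx3, Shox2 and the genes of the 2 peaks closest to a TSS in the top 10 percent by score. Further list members, host genes, neighbours and members of groups of peaks were named after their values were seen, to complete a count.

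The statistics were tested on simulated data first. With 674 of 26220 genes hit, random lists of 30 genes were called in 4.6% of 500 runs at an unadjusted threshold of 0.05. Lists hit 4 times as often were called in 61.6%, and lists hit 10 times as often in 99.4%. Uniform positions were called grouped in 3% of 100 runs, and positions with 50 planted neighbours in 100%. These simulations drew genes and positions with equal weight, as the tests assume. The rates therefore check the calculations and are not error rates for genes of unequal spacing or for uneven open chromatin. Alternatives covered the score minimum, the distance limit, the background, peaks on repeats, merging of close peaks and the window around the TSS. Others were chosen after seeing the data: the host gene in addition to the nearest gene, merged peaks in the test of grouping, and leaving out the peaks in Gabpa or in either of the 2 stretches of chromosome 3. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.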

Results

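ISL1 is a LIM-homeodomain transcription factor of the sinoatrial node, the natural pacemaker of the heart. Its binding was profiled by chromatin immunoprecipitation and sequencing in pacemaker cells of neonatal ICR mice at postnatal day 1 to 3. The cells carried a green fluorescent histone reporter driven from Hcn4, the gene of the main pacemaker channel, and were purified by flow sorting. The series held 2 libraries, 1 ISL1 immunoprecipitate and 1 input DNA, and the peak list of the ISL1 library was analysed here. There was no replicate, so every test below describes this list and no interval covers variation between animals or preparations. The question was which genes ISL1 binds near in pacemaker cells.

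The list held 1483 peaks on 20 chromosomes in mm9 coordinates, each 144 bp from start to end. The authors' peak score had a median of 15.1, quartiles of 12.3 and 17.8, and a range of 8.21 to 84.8. All 1483 scores were whole multiples of a step of 1.37 after rounding to 3 digits. If a step stands for 1 tag, the lowest score rests on 6 tags (exact Poisson 95% interval 2.20 to 13.1), the median on 11 (5.49 to 19.7) and the highest on 62 (47.5 to 79.5). These intervals cover counting error only. On the score scale the interval of the median peak ran from 7.51 to 26.9, which holds both the lowest score and the 90th percentile (23.3); 52 peaks had a score above 30. The scaling of the scores was not stated with them. Under HOMER's usual scaling such a step would put the library at about 7310000 tags.

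ISL1 peaks lay mostly far from promoters. Of the 1483 peaks, 798 were intergenic (53.8%, exact Clopper-Pearson 95% interval 51.2 to 56.4) and 605 intronic (40.8%, 38.3 to 43.3). Another 48 carried the promoter annotation (3.24%, 2.40 to 4.27), 10 lay in exons and 5 in 3′ UTRs. These shares were not compared with those of the genome, so they do not show avoidance of promoters. The median distance to the nearest transcription start site (TSS) was 83.4 kb, with quartiles of 30.2 and 198 kb. Within 1 kb of a TSS there were 53 peaks (3.57%, 2.69 to 4.65), within 10 kb 169 and within 100 kb 822. Of the 605 intronic peaks, 149 lay in intron 1 of their transcript (24.6%). For 167 of the 599 intronic peaks whose host gene could be matched, the nearest TSS belonged to another gene.

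Of all peaks 872 lay downstream of the nearest TSS (58.8%, exact binomial p = 1.3e-11, two-sided) and 611 upstream. Of the 432 intronic peaks inside the gene of the nearest TSS, 401 lay downstream of that TSS and 31 upstream. The test of all peaks against an even split does not set such peaks apart, and it takes grouped peaks as independent. Among intergenic peaks alone, a subset not named in the plan, 373 lay downstream (46.7%) and 425 upstream (exact binomial p = 0.0709, two-sided). Within 1 kb the balance was the other way, with 43 peaks upstream and 10 downstream. Peaks within 1 kb of a TSS had lower scores than the 1430 others, with a median of 12.3 (quartiles 10.9 and 15.1) against 15.1 (12.3 and 17.8; permutation p = 0.00518, 100000 resamples, two-sided). That difference equals 2 score steps and holds across peaks of the list, not for single peaks.

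**Figure D1:**
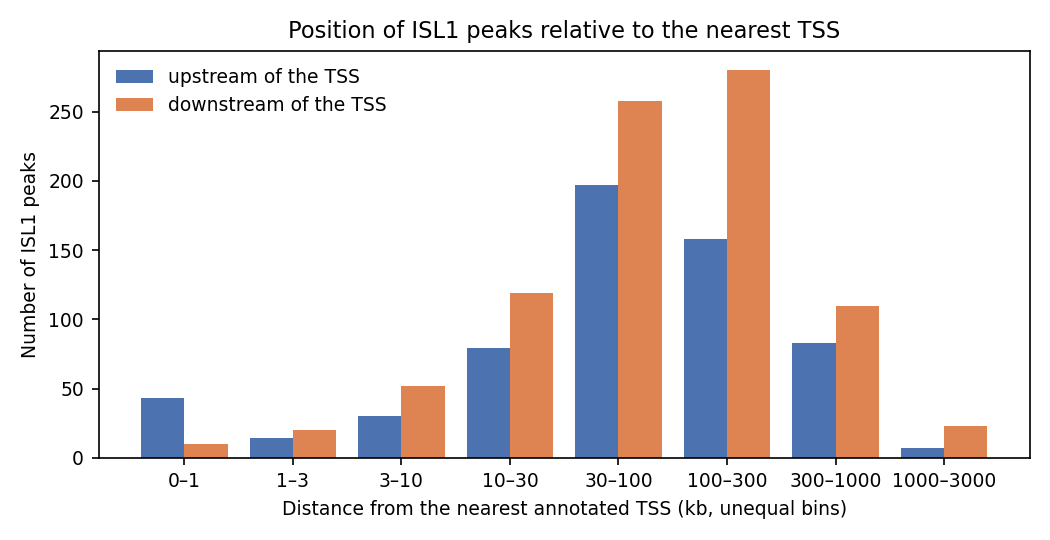
Number of ISL1 peaks (y axis) by distance from the nearest annotated TSS in kb (x axis, bins of unequal width), upstream in blue and downstream in orange. The 0 to 1 kb bin holds 43 upstream and 10 downstream peaks, and the 100 to 300 kb bin holds 158 and 280.

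The strongest peak of the list lay in intron 1 of Unc5c, a netrin receptor of axon guidance, at chromosome 3 141138839 to 141138983 (mm9), 10.4 kb from the TSS. Its score was 84.8 (65.0 to 109 if steps are tags). Together with 8 further peaks in the same intron, of scores 12.3 to 26.0, it spanned 106 kb, and 1 intergenic peak lay 69.0 kb upstream of the gene. Among other high peaks within 100 kb of a TSS, Csrnp3 had 1 of score 41 in intron 3 (chromosome 2 65820229 to 65820373). Tspan12, a tetraspanin gene, had 1 of 39.7 in intron 5 (chromosome 6 21772777 to 21772921). Fap, the gene of fibroblast activation protein, had 1 of 38.3 in intron 2, and Tspan8 1 of 38.3 in intron 8. Intergenic peaks of score 38.3 lay nearest Isoc1, Sh3glb1 and the microRNA gene Mirlet7j. An intergenic peak of score 41 lay 40.8 kb from the noncoding gene 4930528P14Rik, and Eif3h, a translation initiation factor gene, held 1 of 35.6 in intron 3.

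Peaks were grouped along the chromosomes. Of the 1483 peaks, 199 (13.4%) had another peak within 10 kb, 9.88 times the mean of 20.1 in 10000 draws of uniform positions (one-sided permutation p = 0.0001, the smallest the draws can give). The draws model neither mappability nor open chromatin, so the excess is over even placement only. Merging peaks within 1 kb of each other, an alternative chosen after seeing the data, left 110 peaks and a 5.74-fold excess. At a limit of 50 kb, 431 peaks formed 189 groups, and 8 groups held 4 peaks or more. These lay nearest Unc5c (9 peaks), Atp5j (6), the forkhead gene Foxp2 (5), 4930528P14Rik, Eif3h, 8430436N08Rik, 2810442N19Rik and 4930405A10Rik (4 each). The 4 peaks listed under the noncoding 2810442N19Rik, with scores of 13.7 to 24.6, lay at chromosome 1 163947226 to 163975266, and 3 of them were in introns 16 and 17 of Dnm3, a dynamin gene.

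The 6 peaks listed under Atp5j differed in kind from the rest. All 6 lay in exons of the adjacent gene Gabpa, which encodes an ETS-family transcription factor, at chromosome 16 84841577 to 84860735. They fell in exons 3, 5, 6, 8, 9 and 10 of 10, with scores of 10.9 to 28.7, and none fell in an intron. Elsewhere 4 of 609 peaks in an intron or exon were exonic (0.657%, 0.179 to 1.67). The 10 exonic peaks of the list were thus 6 in Gabpa and 4 in other genes.

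**Figure D2:**
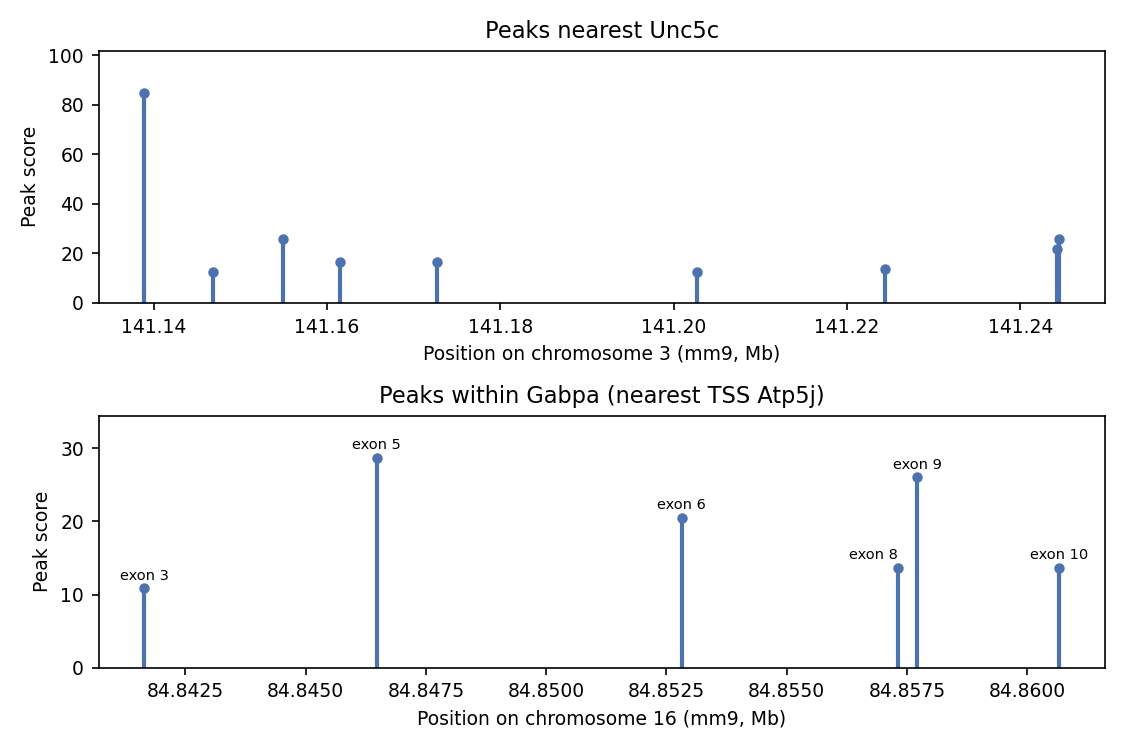
Peak scores (y axis) by position in mm9 (x axis, Mb) for the 9 grouped peaks in intron 1 of Unc5c on chromosome 3 (top) and the 6 peaks within Gabpa on chromosome 16 (bottom); each line with a dot is 1 peak. The highest Unc5c peak reaches 84.8, and each Gabpa peak is marked with the exon that holds it.

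By gene, 675 genes were nearest to at least 1 peak within 100 kb, and 107 of them to 2 or more. Random draws over 26220 genes of equal weight gave a mean of 12.6 such genes and at most 28 (permutation p = 0.0001, one-sided, the smallest the draws can give). Equal weight ignores the size of genes and the space between them. Besides the genes above, Dact1, Fign and Runx1t1 each had 4 peaks, with highest scores of 19.2, 17.8 and 13.7. Dact1 encodes a modulator of WNT signalling, and 1 of the 4 Fign peaks lay 0.011 kb from its TSS. The aminopeptidase gene 2010111I01Rik had 4 within 100 kb, the highest of 23.3.

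None of the 1483 peaks analysed had Hcn4, Tbx3 or Shox2 as its nearest gene. Tbx3 and Shox2 encode transcription factors of the pacemaker programme. Isl1 itself was nearest to 2 intergenic peaks, both far upstream: chromosome 13 117284406 to 117284550 at 185 kb (score 10.9) and 117299338 to 117299482 at 200 kb (score 15.1). In the gene order of the reference table, none of the 3 genes on either side of Hcn4 was nearest to a peak. Among the 3 genes on either side of Tbx3, Tbx5 had a peak of score 16.4 at 129 kb from its TSS (chromosome 5 120413278 to 120413422). AW549542, also among them, was nearest to 2 peaks. Among the 3 genes on either side of Shox2, Veph1 and Ccnl1 were each nearest to 2 peaks, the highest of 24.6 and 17.8. These are places in gene order only, and the distances of these peaks from Tbx3 or Shox2 were not measured. Of the peaks in the top 10 percent by score, the closest to a TSS lay 0.067 kb upstream of the noncoding 8430436N08Rik (chromosome 4 7487696 to 7487840, score 23.3). The next lay 2.44 kb upstream of Prl8a2, a gene of the prolactin family (score 27.4).

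Genes of 6 of the 16 fixed lists were nearest to a peak within 100 kb more often than other genes (Fisher's exact test, Benjamini-Hochberg adjusted over the 16 lists). The highest odds ratio within 100 kb was that of the list of LIM-complex members and homeodomain partners. It had 8 of 22 genes near a peak (36.4%) against 2.54% of other genes, an odds ratio of 21.9 (exact 95% interval 7.93 to 56.1, Fisher's exact adjusted p = 6.8e-07). Among them were the homeodomain genes Meis2 and Pbx3, the LIM-only genes Lmo1 and Lmo4, and the corepressor genes Tle1, Tle3 and Tle4. Meis2 had a peak of score 27.4 in intron 7 (chromosome 2 115827160 to 115827304). Tle3 had 1 of 21.9 at 34.9 kb upstream, and Pbx3 1 of 20.5 in intron 2.

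Of the 36 pacemaker ion channel and calcium clock genes, 6 were near a peak (odds ratio 7.64, 2.59 to 18.7, Fisher's exact adjusted p = 0.00228). Itpr2, a calcium release channel, had a peak of score 21.9 at 35.0 kb (chromosome 6 146485699 to 146485843). Cacnb2, a calcium channel subunit, had 1 of 15.1 in intron 2, and Camk2d, a calcium-dependent kinase, had 3 of 12.3 to 15.1. The anchoring gene Ank2 had 1 intergenic peak of 13.7. The peaks of Atp2a2, the calcium pump of the sarcoplasmic reticulum, and of its inhibitor Pln lay inside neighbouring genes: a 3′ UTR of Ift81 (13.7) and intron 3 of Cep85l (9.58). The 3 peaks of Camk2d and the 1 of Ank2 lay in a 297 kb stretch of chromosome 3. Without that stretch 4 genes were left (odds ratio 4.77, Fisher's exact adjusted p = 0.0421). Among peaks at or above the 75th percentile of score, 1 of the 36 genes remained and the list no longer passed (Fisher's exact adjusted p = 0.451).

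Of the 33 autonomic and cyclic AMP signalling genes, 4 were near a peak (odds ratio 5.25, 1.34 to 15.0, Fisher's exact adjusted p = 0.0261). They were Popdc2 and Popdc3, which encode cyclic AMP-binding membrane proteins, the phosphodiesterase gene Pde3a, and Camk2d, which also counted above. The Popdc2 peak lay in its promoter, 0.09 kb upstream of the TSS (chromosome 16 38362097 to 38362241, score 15.1). This call was lost without the 116 peaks on repeats (Fisher's exact adjusted p = 0.114), without the Camk2d to Ank2 stretch (0.138) and above the 75th percentile, where no gene remained.

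The sarcomere list had 4 of 30 genes near a peak (odds ratio 5.86, 1.48 to 17.0, Fisher's exact adjusted p = 0.0223). They were the Z-disc genes Pdlim5 (26.0), Nebl (24.6) and Pdlim3 (17.8) and the M-band gene Myom1 (12.3). The Pdlim3 peak lay 0.317 kb upstream of the TSS (chromosome 8 46970450 to 46970594), and that of Pdlim5 in intron 3. The developmental signalling list had 6 of 39 genes (odds ratio 6.94, 2.37 to 16.9, Fisher's exact adjusted p = 0.00238). The ligand Wnt11 (30.1), the receptors Fzd1 (24.6) and Bmpr1b (17.8), Jag1 (16.4 within 100 kb), Tcf7l2 and Bmp6 made up the 6. The Wnt11 peak lay in intron 13 of Uvrag, 89.4 kb away. The axon guidance list had 5 of 29 genes (odds ratio 7.95, 2.36 to 21.3, Fisher's exact adjusted p = 0.00315): Unc5c, Robo2, Sema3d, Sema3c and Nrp2. At any distance 17 of the 29 were nearest to a peak (odds ratio 36.2, Fisher's exact adjusted p = 3.7e-16), above the LIM list at any distance (17.6). With the host gene of each peak counted too, 11 axon guidance genes were hit (odds ratio 18.8, Fisher's exact adjusted p = 1.0e-08). Neither count corrects for gene spacing or gene length. The 59 peaks nearest to axon guidance genes lay at a median of 250 kb from the TSS. Above the 75th percentile of score the LIM list stood at 36.9 and the sarcomere list at 13.8. At any distance the sarcomere list stood at 3.88 and the pacemaker list at 5.06. Above the median the developmental list stood at 10.6 and the autonomic list at 9.95, all 6 of these values passing.

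Unc5c, Bmpr1b and Pdlim5 are neighbours, and their 14 peaks lay in a 950 kb stretch of chromosome 3 (141059492 to 142009023), so these 3 lists were not independent. Without that stretch the sarcomere list no longer passed (3 genes, Fisher's exact adjusted p = 0.108). The axon guidance and developmental lists still did (Fisher's exact adjusted p = 0.0243 and 0.0162). Among peaks at or above the 75th percentile of score, 2 axon guidance genes were left and that list no longer passed (Fisher's exact adjusted p = 0.0916). When only peaks within 10 kb of a TSS were used, none of the 16 lists passed, the lowest Fisher's exact adjusted p being 0.131 for the LIM list with 2 genes.

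**Figure D3:**
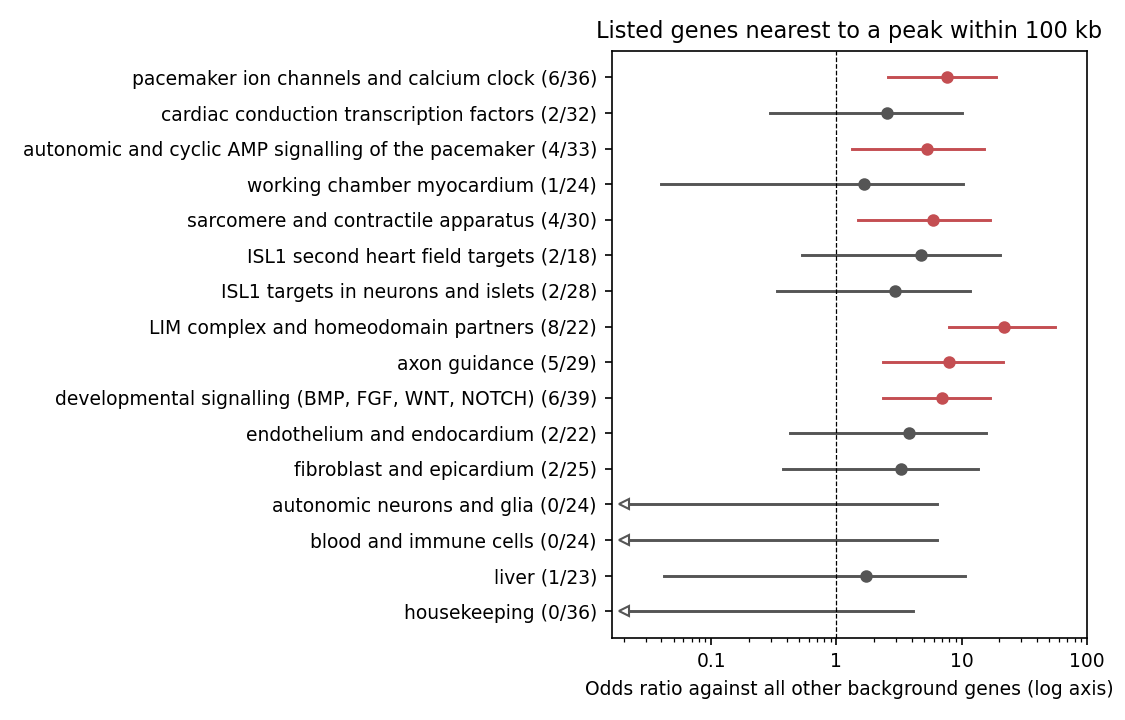
Odds ratio (x axis, log scale) for the genes of each list being nearest to a peak within 100 kb, against all other background genes; lines are exact 95% intervals, cut at the left edge, numbers are genes near a peak over list members, and red marks lists with an adjusted p below 0.05. Open arrows stand for an odds ratio of 0; the LIM list stands highest at 21.9, and 6 of the 16 lists are red.

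The list of cardiac conduction transcription factors did not pass, with 2 of 32 genes near a peak (odds ratio 2.53, 0.293 to 10.0, Fisher's exact adjusted p = 0.289). These were Meis2 and Tbx18, a T-box gene with a peak of score 16.4 at 81.9 kb. At any distance 11 of the 32 were nearest to a peak, among them Tbx5, Irx3, Irx4, Nr2f1, Nr2f2 and Mef2c (odds ratio 13.3, Fisher's exact adjusted p = 1.19e-07). Of the 22 peaks nearest to genes of this list, 2 lay within 100 kb, and the median distance of the 22 was 173 kb. Gene spacing was not corrected for. Of 18 second heart field targets of ISL1, Wnt11 and Nrg1 were near a peak (odds ratio 4.75, Fisher's exact adjusted p = 0.176; 4 genes at any distance, p = 0.0113). Of 28 ISL1 targets known from neurons and islets, Slc30a8 and Ebf2 were (odds ratio 2.92, Fisher's exact adjusted p = 0.258; 4 genes at any distance, p = 0.0418). When the gene whose body holds a peak was counted too, an alternative chosen after seeing the data, the conduction and second heart field lists passed with 4 genes each (Fisher's exact adjusted p = 0.036 and 0.00581). The working myocardium list had 1 of 24 genes, Nebl (odds ratio 1.65, Fisher's exact adjusted p = 0.572).

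Lists of other cell types did not pass. Ets1 and Emcn were the 2 of 22 endothelial genes near a peak (odds ratio 3.80, 0.430 to 15.7, Fisher's exact adjusted p = 0.218). Tcf21 and Vim were the 2 of 25 fibroblast and epicardial genes (odds ratio 3.30, 0.377 to 13.4, Fisher's exact adjusted p = 0.239). The liver list had 1 of 23, Tdo2 (odds ratio 1.72, 0.0417 to 10.7, Fisher's exact adjusted p = 0.572). Each of these intervals holds the odds ratio of the pacemaker list (7.64), so a contrast between cell types is not shown. None of 24 autonomic neuron and glia genes, 24 blood and immune genes or 36 housekeeping genes was near a peak. The upper 95% bounds of their odds ratios were 6.31, 6.31 and 4.09, so a moderate excess was not excluded by lists of this size.

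Peak density differed between chromosomes. The 19 autosomes held 1471 peaks, 0.652 per Mb of the length between their first and last peak, from 0.319 on chromosome 7 to 0.981 on chromosome 3. Chromosome X held 12 (exact Poisson 95% interval 6.20 to 21), or 0.0769 per Mb, which was 0.118 times the autosomal density (0.061 to 0.206). At that density 102 peaks would fall on X (exact binomial p = 5.0e-28, two-sided, a test chosen after seeing the data). The test and the intervals take peaks as independent and the density as even. As autosomes differed and peaks were grouped, both understate the spread between chromosomes. The peak names are numbered within each chromosome and skip numbers: 107 of 158 on chromosome 11, 14 of 26 on X and 385 of 1868 in all. What the skipped numbers stand for is not known, so the densities hold for the peaks analysed only.

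**Figure D4:**
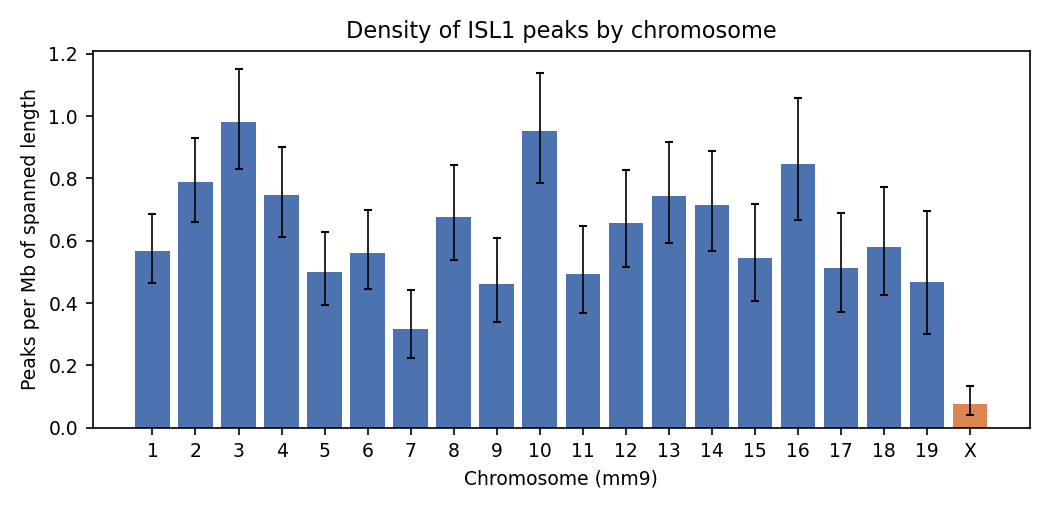
ISL1 peaks per Mb of the length from the first to the last peak (y axis) on each chromosome of mm9 (x axis); error bars are exact Poisson 95% intervals. Chromosome X, in orange, stands at 0.0769 per Mb, below each of the 19 autosomes (0.319 to 0.981).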

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

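All tests in this part were chosen only after the results were seen. Signals in parts of the peak table outside the comparisons were the exon numbers of peaks, the numbering of peak names and the repeat annotation.

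The 6 peaks in exons of Gabpa stood out because exon numbers were used in no comparison and all 6 peaks of the gene were exonic. Independent placement of exonic peaks over genes is argued against, though the measure was chosen because of Gabpa. Exon labels were shuffled over 609 peaks of 435 matched host genes, with the peaks in Gabpa and all 10 exonic peaks included. No gene reached more than 3 exonic peaks in 10000 shuffles (permutation p = 0.0001, the smallest they can give). The shuffles search all genes, though they treat peaks of a gene as independent. Spliced Gabpa sequence among the reads, such as a complementary DNA or a retrocopy, is a candidate explanation that stays open, since 6 of the 10 exons held a peak and the exonic placement is what prompted it. ISL1 binding at these exons and the input, which was not analysed here, were not tested.

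Peak names skip 385 of 1868 numbers (20.6%), and 107 of them fall on chromosome 11. On the chromosomes other than 11, 47.8% of the skipped numbers (exact 95% interval 41.8 to 53.9) lay in the first part of the numbering, up to the midpoint, where scores are higher. On chromosome 11 the share was 65.4% (55.6 to 74.4). Whether these numbers were dropped by the peak caller or in another way is not known.

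In the repeat annotation, 5 peaks lay on RLTR22_Mus elements, a long terminal repeat of endogenous retroviruses, on 5 chromosomes. Their scores were 34.2, 19.2, 13.7, 13.7 and 12.3, the highest at chromosome 19 12394657 to 12394801, 2.59 kb from Olfr1437.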

How the results depend on the processing

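Besides the tests fixed before the data were examined, the host-gene assignment, the merging in the test of grouping, and leaving out Gabpa or the 2 chromosome 3 stretches were chosen after the results were seen. Of 188 alternative values, 146 kept their direction and side of the threshold or their size. The score difference between promoter and distal peaks kept both under each alternative. Leaving out unplaced sequences removed 0 peaks and tests nothing, yet its values are among the 146. So are lists with 0 genes, which a smaller set of peaks can only leave at 0. The 146 therefore overstate how much was put to the test. Draws weighted by genome length, lists matched on gene length and motifs were not run. A score at or above the median of 15.1 left 758 peaks, with 2.11% within 1 kb of a TSS, 36 genes with several peaks and 71 peaks with a neighbour within 10 kb. At or above the 75th percentile of 17.8 these were 436, 1.61%, 17 and 37; the lower counts follow from the smaller list, and the lower share goes with the lower scores near a TSS. Within 5 kb of a TSS lay 7.75% of peaks, and within 50 kb of another peak 431. Genes with several peaks numbered 275 at any distance and 5 within 10 kb, and 110 peaks had a neighbour after merging. For genes with several peaks and for peaks with a neighbour, the excess over random draws held in each of these settings, with a permutation p of at most 0.002. For the lists, values are odds ratios. Above the median the neuron and islet list fell to 0. Above the 75th percentile the pacemaker list stood at 3.52 and the axon guidance list at 9.16, neither passing, and the autonomic signalling, neuron and islet, endothelial and liver lists at 0. Within 10 kb, the pacemaker (4.59), autonomic signalling (10.4), sarcomere (5.54) and LIM (16.2) lists no longer passed. The conduction, working myocardium, second heart field, neuron and islet, axon guidance, developmental, endothelial and liver lists were at 0 there. Fewer genes hit at these limits account for part of the losses by construction. At any distance the conduction (13.3), second heart field (7.21) and neuron and islet (4.21) lists passed, and autonomic neurons and glia moved to 1.09. Without repeats the autonomic signalling list fell to 4.14 and the liver list to 0. Counting the host gene too, the conduction (4.36) and second heart field (8.73) lists passed. Without the chromosome 3 stretch from Unc5c to Pdlim5 the sarcomere list fell to 4.24, and without that from Camk2d to Ank2 the autonomic signalling list to 3.81, each having lost 1 of 4 genes. Other causes were not tested. What depth limits was not tested, since total reads were not analysed here.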

Other observations

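The tests of gene families and of chromosome X were chosen only after the results were seen; the list tests within 10 kb were planned, but their use to weigh gene spacing was chosen after. Olfactory receptor genes were seldom the nearest gene of an ISL1 peak: 1 of 1126 was so within 100 kb, against 673 of 25094 other genes (odds ratio 0.0323, 0.000815 to 0.181). This was the only 1 of 940 families of gene symbols with at least 4 members to pass (Fisher's exact adjusted p = 6.0e-09), and its single peak, at Olfr1437, lay on a retroviral repeat. The family of symbols starting with Vmn went the same way without passing, with 0 of 360 genes (Fisher's exact adjusted p = 0.0686). The family tests take genes as independent and do not correct for gene spacing. Close spacing within a family can therefore not be told apart from a lack of binding. The Tle corepressor family had 3 of 7 genes near a peak (odds ratio 28.5, Fisher's exact adjusted p = 0.172) and Foxp 2 of 4, Foxp1 and Foxp2 (38.0, Fisher's exact adjusted p = 0.469), neither passing over all families.

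Among the 48 promoter peaks, those of score 17.8 or more included Dnm3os, the noncoding host of a microRNA cluster (19.2), Gem, a small GTPase gene (19.2), Foxp2 (17.8) and Pdlim3 (17.8). The Dnm3os peak lay at chromosome 1 164147749 to 164147893, 0.067 kb downstream of its TSS. Of all peaks 116 (7.82%) lay on annotated repeats, 41 on long terminal repeats, 36 on LINE and 23 on SINE elements. The axon guidance genes Robo1, Slit2 and Efnb2 were nearest to peaks beyond 100 kb only. The highest were a peak of score 34.2 at 695 kb for Robo1 and 1 of 35.6 at 487 kb for Slit2.

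Chromosome X held 12 peaks where 102 would follow from the autosomal density. With the skipped numbers counted too, X had 0.167 peak numbers per Mb (upper 95% bound 0.244) against 0.398 on the lowest autosome. As it is not known what the skipped numbers stand for, this does not settle whether X candidates were removed against the input. A single accessible X copy per cell, with a fixed score minimum, could lower the count: halving the autosomal scores leaves 39.0 expected peaks at the lowest score of the list, 6 steps, above the interval of the 12 observed (6.20 to 21). With both counted from 7 steps it leaves 22.1 against 11 (5.49 to 19.7), also above the interval. From 8 steps it leaves 14.0 against 11, inside the same interval. A halved dose thus left an expected number above the interval at the list's own minimum and at 7 steps, but not at 8. The expected numbers rest on the mean autosomal density, and the intervals leave out the spread between autosomes (0.319 to 0.981 per Mb). The comparison therefore cannot decide whether a halved dose falls short. As the dose is also assumed, a single accessible X copy stays open as a cause, whole or in part. The sex of the animals and mappability were not tested.

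The excess of the LIM and axon guidance lists could come from wide intergenic space around developmental genes. Within 10 kb, where flanking space counts little, the LIM list had an odds ratio of 16.2 (1.82 to 67.4, Fisher's exact adjusted p = 0.131, 2 genes) and the axon list 0 (0 to 21.9), too few genes to decide. Of the 59 peaks nearest to axon guidance genes 15 lay within 100 kb, and of the 23 nearest to LIM-list genes 9, against 822 of all 1483. Their median distances were 250 and 145 kb, where the other peaks had 81.0 and 83.1 kb, which goes with wide spacing. Binding near these genes because of their function remains a hypothesis that was not tested apart from gene spacing.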
